A study of Mus musculus with 8 samples.

How the data were processed

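The samples were 8 RNA sequencing libraries of mouse regulatory T cells (Tregs), 2 from each combination of genotype (Foxp3-Cre with intact Pparg, here WT, or Foxp3-Cre with floxed Pparg, here KO) and tissue (skin or spleen). Per the labels' protocols, 1000 sorted cells went into each library, cDNA was primed with oligo(dT) and amplified by limited PCR, libraries were made by tagmentation, and 2 reads of 25 bases were sequenced per fragment. The deposited values are raw whole-number counts per gene symbol, and per the submitters' processing notes the tools were STAR 2.7.3a and featureCounts with genome build mm10. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here, so genes with near-identical copies and antisense genes are reported as uncertain.

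The count table held 55011 gene symbols, of which 28902 had a count in any library, and no line of it named anything other than a gene. Library totals ran from 3115832 to 4466963 counts, and 12414 genes passed edgeR's filterByExpr with its minimum count of 10. The libraries were scaled by TMM, and all gene levels are given in CPM, counts scaled to a common TMM-normalised library size, as mean and SD over n = 2 libraries. Levels of H2-Aa, H2-Ab1, Cd8a, Pecam1, Epcam, Krt5, Lyz2 and Xist are instead CPM of the total count. The main test was edgeR's robust quasi-likelihood test with 1 coefficient per group fitted to all 8 libraries, with Benjamini-Hochberg adjustment over the 12414 genes and a threshold of 0.05. The common biological coefficient of variation was 17.5%. The edgeR fold changes were computed with a prior count of 2, which shrinks them. At low counts they are therefore smaller than the ratio of the CPM means printed beside them. Fold changes carry their standard errors (SE) on the log2 scale. The 6 comparisons were KO against WT in skin, in spleen and averaged over both tissues, the difference of the genotype effects between the tissues, and skin against spleen in WT and in KO.

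Gene lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 30 lists of a comparison. An estimated correlation and the fry rotation test were the alternatives. The counts of members past the threshold are given over all genes and adjusted over the list alone. The lists, the groups, the tests and a first set of alternatives were chosen before the data were examined. A tissue signature was defined as the 200 genes of smallest p with an adjusted p under 0.05 and a log2 fold change over 1 between skin and spleen in WT. It was built for each direction and then tested in the skin genotype effect. The overlaps of gene calls were tested with Fisher's exact test, one-sided, over all tested genes.

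Genes were named by a rule set in advance. Pparg and Foxp3 come first in each comparison. Of genes past the threshold whose libraries did not overlap between the groups and whose average log2 CPM was at least 2, the 12 with the largest change in each direction were eligible. Overlap was not considered for the difference between tissues. Where fewer than 10 passed, the genes of smallest p up to 10 were added. Up to 4 members of each list with the smallest p were also eligible. Predicted or clone-named genes, pseudogenes, receptor segments and sex-linked genes were left out of the ranking. Genes named because they are shared by a pair of call sets, as marker levels, or as further list members were chosen after their values were seen. Some genes that met the rule are not reported here.

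For a group with 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group's libraries. With 1 to 3 counts, the ratio of pooled counts is given with an exact binomial 95% interval. The amplified reads carry no molecular identifiers, so these intervals and floors cover counting error only. Positions are 1-based and come from GENCODE M21 on the same genome build, in which 12217 of the tested genes (98.4%) were found by symbol.

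The fits were tested on a single draw of simulated counts per comparison, with 200 changed genes. The changed genes were taken only from those above a minimum mean CPM, so recovery of genes at lower levels was not tested. In the skin comparison (12083 genes) 55 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were recovered, and in the spleen comparison (12082 genes) 43 and 89. Unchanged genes made up 9.49% of the 158 simulated calls in skin and 7.04% of the 142 in spleen, against a nominal 5%. Alternatives covered other scalings, DESeq2, limma-voom with and without quality weights, other low-count filters, a fit to the compared groups only, replicate blocks, a fold threshold of 1.5 and leaving out each library. A fit without robust estimation, a GC content offset with and without the block, an additive model, and a correlation without sex-linked genes or with the GC offset were chosen after seeing the data. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.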

Results

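Regulatory T cells are CD4 T cells that express Foxp3 and restrain immune responses. Their transcriptomes were compared in skin and spleen of young mice (2 weeks old per the series' design text, day 13 in the sample titles) with or without the gene for PPARγ, a nuclear receptor that responds to fatty acids. The 8 libraries formed 4 groups of 2, namely WT skin, KO skin, WT spleen and KO spleen. Totals were 4466963 and 3115832 counts in WT skin, 4116847 and 3568695 in KO skin, 3967008 and 3235884 in WT spleen, and 3403720 and 3882878 in KO spleen. Between 17262 and 19274 genes were detected per library. Replicate 1 of each group carried Xist and replicate 2 carried Y genes, so the replicates of a group came from different animals or pools. The labels do not say how many animals a library holds, and p-values measure only the spread between these samples, sex included. Replicate counts differed by more than sampling noise in every group, with a chi-square per degree of freedom of 4.48 to 7.32. The first principal component held 64.6% of the variance and separated the tissues, with WT skin at -66.5 and -69.4, KO skin at -49.7 and -52.9, WT spleen at 55.5 and 54.2, and KO spleen at 62.7 and 66.

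Pparg (chromosome 6, 115360951 to 115490399, mm10) was lower in each KO library than in each WT library of the same tissue. Its level was 75.7 and 59.8 CPM in WT skin, 8.46 and 13.3 CPM in KO skin, 22.5 and 12.3 CPM in WT spleen, and 2.16 and 1.66 CPM in KO spleen. It was 6.04-fold lower in KO skin (edgeR adjusted p = 0.000609) and 7.41-fold lower in KO spleen (edgeR adjusted p = 0.00418). Both folds are shrunk by the prior count of edgeR's fit. Without KO spleen replicate 2 the spleen difference had an edgeR adjusted p of 0.0602, and for limma-voom the adjusted p of Pparg in spleen was 0.0716. Gene-level counts do not show which exons the remaining reads cover. Foxp3, the lineage-defining transcription factor, was at 355 ± 35.2 CPM in WT skin, 294 ± 47.2 in KO skin, 189 ± 20.6 in WT spleen and 194 ± 4.90 in KO spleen (SD, n = 2). Its genotype effect did not pass in skin (log2 fold change -0.27, edgeR adjusted p = 0.486) or in spleen (log2 fold change 0.04, edgeR adjusted p = 0.993).

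**Figure D1:**
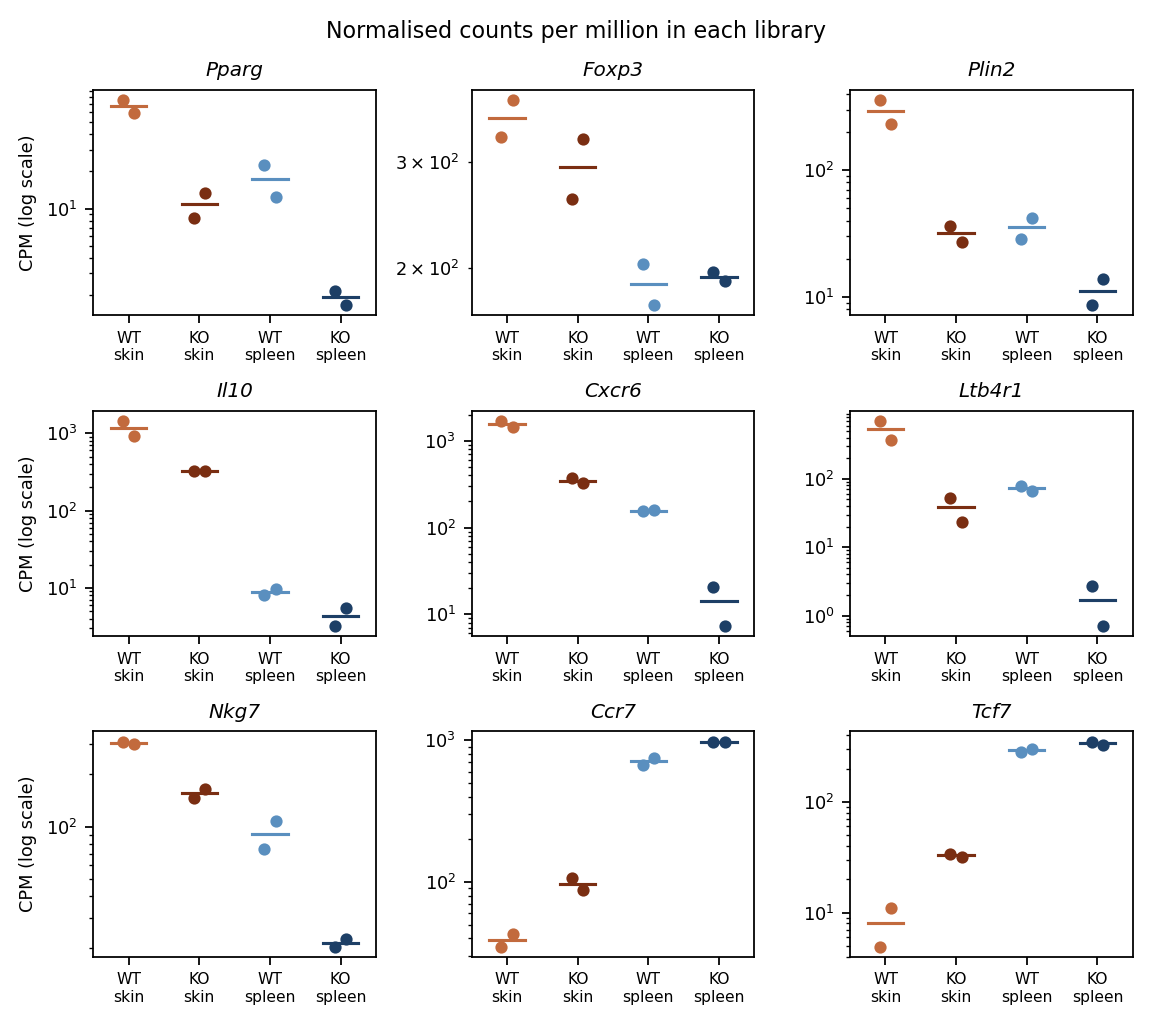
Normalised CPM (log axis) of 9 genes in each library, with points for libraries and lines for group means. Pparg, Plin2, Cxcr6, Ltb4r1 and Nkg7 were lower in both KO libraries than in both WT libraries of the same tissue, and Ccr7 was higher.

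The first comparison asked what the loss of Pparg changed in skin Tregs. Plin2, which coats lipid droplets, fell 9.15-fold, from 296 ± 88.6 to 31.8 ± 6.59 CPM (SD, n = 2). Il10, an anti-inflammatory cytokine of effector Tregs, fell 3.63-fold, from 1189 ± 372 to 327 ± 3.71 CPM. Tcf7, a transcription factor of naive and memory-like T cells, rose 4.14-fold, from 7.98 ± 4.31 to 33.0 ± 1.49 CPM, and Ccr7, a receptor that guides T cells to lymph nodes, rose 2.50-fold, from 39.0 ± 5.68 to 97.4 ± 12.8 CPM. Jup, which encodes the junction protein plakoglobin, fell 12.4-fold from 68.5 ± 26.9 to 5.04 ± 0.724 CPM.

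Among other genes lower in KO skin, the chemokine receptor gene Xcr1 changed by -2.96 ± 0.416 (log2 ± SE), the coagulation factor gene F13a1 by -2.80 ± 0.388, and Gpt2, an alanine aminotransferase, by -2.09 ± 0.280. Frmd5 changed by -2.16 ± 0.302, the sugar-phosphate transporter gene Slc37a2 by -2.15 ± 0.305, and the collagen-binding integrin gene Itga1 by -2.64 ± 0.548. Dmxl2 (-3.77 ± 0.702), the protease gene Ctsh (-3.52 ± 0.703) and Chadl (-2.93 ± 0.603) also fell. WT skin replicates 1 and 2 differed, with 26.9 and 5.69 CPM for Dmxl2 and 54.5 and 17.8 CPM for Ctsh. Without WT skin replicate 1 the log2 fold changes were -2.31 for Dmxl2, -2.50 for Ctsh, -2.66 for Chadl and -1.75 for Itga1 and did not pass (edgeR adjusted p = 0.199 to 0.583), nor did these 4 pass without KO skin replicate 1 or 2 (0.103 to 0.382). Among genes higher in KO skin, the surface receptor gene Cd96 changed by 1.34 ± 0.148, the laminin-binding integrin gene Itga7 by 2.12 ± 0.334, Klhl3 by 2.13 ± 0.435, Klhl42 by 2.09 ± 0.394, and the ribosome assembly factor gene Rrs1 by 2.13 ± 0.404. The small GTPase gene Rras2 (1.98 ± 0.346), H2-Ob (1.71 ± 0.338), the non-coding transcript BE692007 (1.71 ± 0.266), Cd7 (1.56 ± 0.323), the interferon-inducible GTPase gene Iigp1 (1.66 ± 0.294) and the proteasome subunit gene Psmd3 (1.41 ± 0.294) also rose. Each of these genes had an edgeR adjusted p under 0.05, the lowest being 0.000115 for Jup and for Ccr7. Among the higher genes, calls ended without WT skin replicate 1 (Itga7, Klhl3, Klhl42, Rrs1, Rras2, Iigp1 and Psmd3), WT skin replicate 2 (Klhl3, H2-Ob and Cd7), KO skin replicate 1 (these but Rras2) or KO skin replicate 2 (Klhl3, Rrs1, Rras2, Cd7, Iigp1 and Psmd3), with an edgeR adjusted p of 0.0503 to 0.292. Those of Iigp1 and Psmd3 also ended without either WT spleen library (0.0922 to 0.1).

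Of the list of tissue Treg effector genes, 4 of 37 tested members fell (Il10, Areg, Lgals3 and Gata3), 1 rose (Bhlhe40) and 32 did not pass. Adjusted over the list alone, 12 fell and 1 rose. Areg, a growth factor of tissue-repairing Tregs, changed by -1.36 ± 0.242. Its call ended without any 1 of the skin libraries except WT skin replicate 2, without either WT spleen library and without KO spleen replicate 2 (edgeR adjusted p = 0.0531 to 0.278). The list was lower as a group (median log2 fold change -0.25, camera adjusted p = 0.00021; adjusted p = 0.487 with an estimated correlation). Of the resting lymphoid T cell list, 2 of 24 members rose (Ccr7 and Tcf7) and 22 did not pass. Adjusted over the list alone, 5 rose and 1 fell. That list was higher as a group (median 0.37, camera adjusted p = 0.00168; adjusted p = 0.452 with an estimated correlation). Of 22 Treg core genes, Izumo1r, a folate receptor family gene also called Fr4, rose by 1.28 ± 0.161 and 21 did not pass (camera adjusted p = 0.626).

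For metabolism, 1 of 24 tested PPAR target genes fell (Plin2), adjusted over the list alone 4 fell, and the list did not pass as a group (median -0.18, camera adjusted p = 0.0536). Of 22 fatty acid oxidation genes none passed alone, although 4 fell when adjusted over the list alone. The list was lower as a group (median -0.18, camera adjusted p = 0.00682; adjusted p = 0.487 with an estimated correlation). For its carnitine shuttle member Cpt1a the level was 193 ± 12.2 CPM in WT and 131 ± 18.2 CPM in KO skin. Of 24 glycolysis and hypoxia genes, 2 rose (the enzyme genes Eno1, by 0.64 ± 0.101, and Tpi1, by 0.45 ± 0.101) and 22 did not pass. Adjusted over the list alone, 8 rose and 1 fell. Without WT skin replicate 1 or KO skin replicate 1 the call of Eno1 ended (edgeR adjusted p = 0.0683 and 0.0549). That list was higher as a group (median 0.20, camera adjusted p = 0.0186; adjusted p = 0.487 with an estimated correlation). None of the 58 oxidative phosphorylation genes and none of the 40 proliferation genes passed by edgeR, and neither list passed by camera (adjusted p = 0.605 and 0.938).

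Of 31 type I interferon response genes, 1 rose (Ifi27l2a, by 0.86 ± 0.164) and 30 did not pass, and 2 rose adjusted over the list alone. The list was higher as a group (median 0.28, camera adjusted p = 0.0358; adjusted p = 0.756 with an estimated correlation). The list of T helper cytokines and regulators was higher as a group (median 0.38, camera adjusted p = 0.0241; adjusted p = 0.452 with an estimated correlation) with none of 15 members past the threshold. Its member Ccr6, a homing receptor, measured 113 ± 41.9 CPM in WT and 234 ± 19.3 CPM in KO skin. Genes that respond to tissue dissociation and heat shock, a marker of handling, were lower as a group in KO skin (median -0.33, camera adjusted p = 5.79e-05; adjusted p = 0.452 with an estimated correlation). Of its 32 members 4 fell (Atf3, by -1.78 ± 0.289, Socs3, Zfp36 and Jun), and 14 fell adjusted over the list alone, so the lower effector genes went together with lower stress genes. Nfkbia, an inhibitor of NF-kB and an early response gene, fell by 0.53 on the log2 scale, while the NF-kB response list did not pass (median 0.01, mean -0.05, camera direction lower, adjusted p = 0.605).

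The B cell list was higher as a group in KO skin (6 tested members, median 0.84, camera adjusted p = 0.0341; adjusted p = 0.452 with an estimated correlation), with no member past the threshold. Most of its genes were near the floor, with a list median of at most 1.12 CPM of the total count in any library. Its member Cd79a had 3 counts in WT and 15 in KO skin, and Ms4a1 was at 0 CPM in the skin libraries. H2-Aa reached 38.1 CPM, H2-Ab1 43.7 CPM and Cd8a 7.04 CPM in KO skin replicate 1, against 2.24, 6.17 and 0 CPM in KO skin replicate 2. The immunoglobulin gene Ighm, a member of that list, was at 610 ± 72.4 CPM in WT skin, 794 ± 55.8 in KO skin, 921 ± 0.619 in WT spleen and 771 ± 160 in KO spleen, and did not pass in skin (edgeR adjusted p = 0.231). The protease gene Ctss of the myeloid list rose in KO skin, from 142 ± 4.51 to 225 ± 48.5 CPM. Pecam1, of the endothelial list, reached 402 CPM of the total count in KO spleen replicate 2. The 12 endothelial genes together summed to 404 CPM in that library, with a median of 0. Epcam, of the Langerhans and dendritic cell list, reached 144 CPM of the total count in WT skin replicate 2, where the median of its list was 0.321 CPM. The keratinocyte gene Krt5 was at most 0.841 CPM and the myeloid gene Lyz2 at most 1.96 CPM in any library. Of 6 tested CD8 T and NK cell markers, the granule gene Nkg7 fell by 0.96 on the log2 scale, while the list had a median of 0.55 (camera adjusted p = 0.605). Without WT skin replicate 1 or KO skin replicate 1 the call of Nkg7 ended (edgeR adjusted p = 0.0501 and 0.113).

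In all, edgeR called 111 of 12414 genes in skin, 38 higher and 73 lower in KO, against 1342 genes at an unadjusted p under 0.05, 684 higher and 658 lower. With upper-quartile scaling the split was 52 higher and 64 lower. Without WT skin replicate 1 the count was 29 (15 higher and 14 lower), without KO skin replicate 1 it was 33 (12 and 21), without KO skin replicate 2 it was 54 (30 and 24), and without WT skin replicate 2 it was 209 (107 and 102), so the excess of lower calls was absent without 3 of the 4 skin libraries. Pparg, Tcf7, Cd96, Ccr7, Izumo1r, Il10, Jup, Plin2, Xcr1, F13a1 and Gpt2 kept their calls in each of 21 alternatives, which the other 30 named genes past the threshold did not. Frmd5 and Slc37a2 lost theirs without WT skin replicate 1 (edgeR adjusted p = 0.0679 and 0.0683).

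In spleen, where the comparison asked for effects of Pparg loss in lymphoid Tregs, genes were called mainly lower in KO. Nkg7, a cytotoxic granule gene, fell 4.14-fold from 91.2 ± 23.1 to 21.5 ± 1.44 CPM (SD, n = 2, edgeR adjusted p = 1.96e-05). Frmd5, a cytoskeletal adaptor gene, fell from 23.6 ± 2.66 to 1.62 ± 0.388 CPM, 11.1-fold after shrinkage by the prior count (edgeR adjusted p = 0.000351). Itga1 had 52 counts in WT and 0 in KO spleen, at least 17.7-fold lower. Iigp1 was the 1 gene called higher, 3.31-fold, from 48.9 ± 1.29 to 163 ± 56.8 CPM (edgeR adjusted p = 0.0289).

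Further genes lower in KO spleen were Zan (log2 change -3.13 ± 0.579 SE), the TNF receptor family gene Tnfrsf8, which encodes CD30 (-2.72 ± 0.497), Gpt2 (-2.49 ± 0.443), the lysosomal membrane gene Lamp1 (-1.88 ± 0.267), Psmd3 (-1.82 ± 0.267), Yipf4 (-1.60 ± 0.253) and the basement membrane gene Nid2 (-1.58 ± 0.274). Values that did not pass included Cxcr6, a chemokine receptor of tissue T cells (157 ± 3.91 CPM in WT and 14.1 ± 9.49 in KO, edgeR adjusted p = 0.0501), and Plin2 (35.3 ± 9.56 and 11.2 ± 3.63 CPM, edgeR adjusted p = 0.0516). Among values above 0 that did not pass were Smyd4 (log2 fold change 1.23, edgeR adjusted p = 0.0675), P4ha1 (0.58, 0.106), Igf2r (0.60, 0.111), the lactate transporter gene Slc16a3 (0.73, 0.111), Uckl1os (2.18, 0.118), Ccr7 (0.46, 0.137), Tsc22d3 (0.94, 0.15) and Tiparp (0.64, 0.168).

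By list, none of 37 tissue Treg effector genes passed alone by edgeR in spleen, and 17 fell and 1 rose adjusted over the list alone. The list was lower as a group (median -0.47, camera adjusted p = 4.1e-09; adjusted p = 0.389 with an estimated correlation). None of the 24 resting lymphoid genes passed alone, and 3 rose adjusted over the list alone. The list was higher as a group (median 0.27, camera adjusted p = 0.00063; adjusted p = 0.389 with an estimated correlation). The type I interferon list was also higher as a group (31 tested, 0 past the threshold, median 0.42, camera adjusted p = 0.000213; adjusted p = 0.508 with an estimated correlation). Single members of other lists fell, namely the replication helicase gene Mcm4 (-0.62 ± 0.119), the NF-kB inhibitor gene Tnfaip3 (-1.11 ± 0.187) and the phosphatase gene Dusp2 (-1.47 ± 0.227). The proliferation, NF-kB and stress lists did not pass (camera adjusted p = 0.748, 0.223 and 0.218). PPAR targets and fatty acid oxidation did not pass either (camera adjusted p = 0.218 and 0.395). Marker lists of other cells lay on both sides of 0 in KO spleen, and none passed as a group. Of 11 tested myeloid genes 9 were above 0 (median 0.20, camera adjusted p = 0.218). All 6 tested B cell genes were below 0 (median -0.51, camera adjusted p = 0.077), as were 5 of 6 Langerhans and dendritic cell genes (median -1.05, 0.0549) and 4 of 6 CD8 T and NK cell genes (median -0.96, 0.077).

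In all, edgeR called 35 genes in spleen, 1 higher and 34 lower, against 972 genes at an unadjusted p under 0.05, 341 higher and 631 lower. Of all 12414 genes 6251 were below 0. The count was 7 without KO spleen replicate 2, 9 and 16 without WT spleen replicates 2 and 1, 119 without KO spleen replicate 1, and 57 and 61 without WT skin replicates 1 and 2. Nkg7 kept its call in each of 21 alternatives, which the other 15 named genes past the threshold did not. Iigp1 lost its call without KO skin replicate 1 or 2, without WT spleen replicate 1 or 2 and without KO spleen replicate 2 (edgeR adjusted p = 0.102, 0.101, 0.449, 0.418 and 0.135). Itga1 lost its call without WT spleen replicate 2 or KO spleen replicate 2 (0.0804 and 0.141). The call of Psmd3 ended without WT spleen replicate 1 or 2 or KO spleen replicate 2 (0.134, 0.111 and 0.141).

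**Figure D2:**
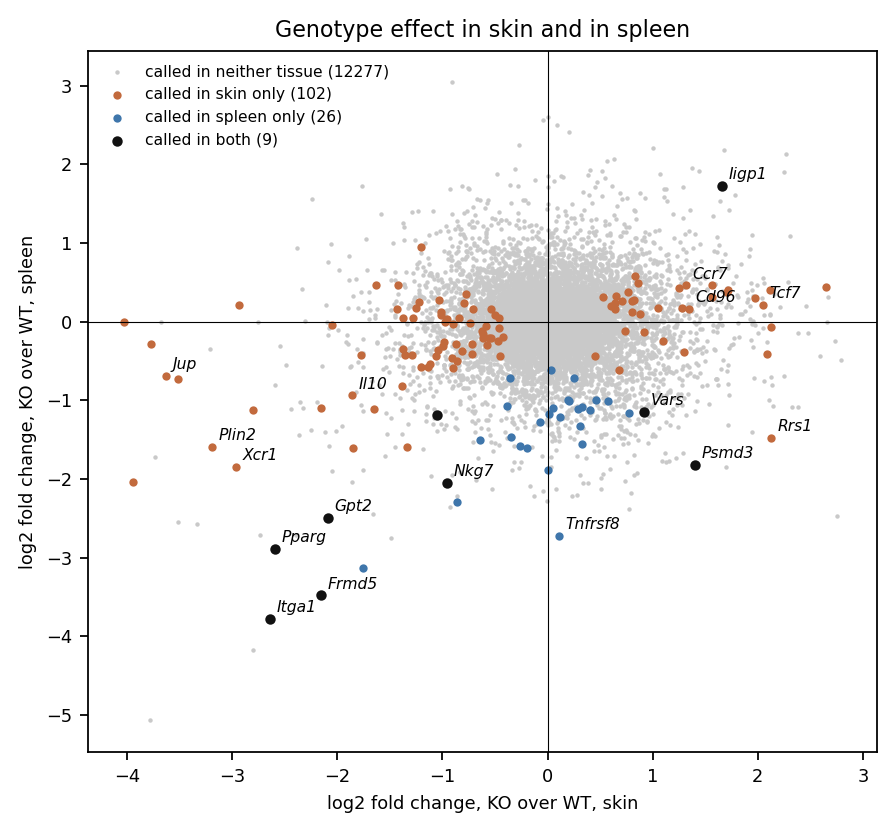
Log2 fold change of KO over WT in skin (horizontal) against spleen (vertical), with 1 point per tested gene, coloured by the tissue in which the edgeR adjusted p was under 0.05. The genes called lower in both tissues include Pparg, Frmd5, Gpt2, Itga1 and Nkg7, and Iigp1 was called higher in both.

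The effect of Pparg loss was then averaged over both tissues. The naming rule kept leading genes whose libraries did not overlap, in the same direction, within each tissue. The averaged test itself does not ask whether the tissues agree, and Tcf7, Cd96 and Jup also differed between them. Cxcr6 fell 7.06-fold (1584 ± 173 to 349 ± 30.1 CPM in skin and 157 ± 3.91 to 14.1 ± 9.49 CPM in spleen, SD, n = 2). Ltb4r1, the receptor for the lipid mediator leukotriene B4, fell 21.5-fold on average (538 ± 237 to 38.3 ± 20.9 CPM in skin and 72.7 ± 10.1 to 1.71 ± 1.4 CPM in spleen). Neither Cxcr6 nor Ltb4r1 was called by edgeR in skin alone or in spleen alone. Plin2 fell 5.25-fold, Frmd5 7.04-fold and Nkg7 2.84-fold. Ccr7 rose 1.85-fold, with 974 ± 2.90 CPM in KO against 708 ± 60.9 CPM in WT spleen.

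Others lower on average were Itga1 (log2 -3.21 ± 0.416 SE), Gpr137b (-2.72 ± 0.546), Zan (-2.44 ± 0.413), Xcr1 (-2.40 ± 0.370), Gpt2 (-2.29 ± 0.264), Jup (-2.16 ± 0.255), F13a1 (-1.96 ± 0.284), and the chemokine receptor gene Ccr1 (-1.47 ± 0.264). The value of Itga1 is not an exact size, since both KO spleen libraries held 0 counts of it. Others higher on average were Iigp1 (1.69 ± 0.203), the antiviral sensor gene Oas3 (1.15 ± 0.251), Rras2 (1.14 ± 0.213), Tcf7 (1.13 ± 0.142), Prelid2 (1.11 ± 0.251), H2-Ob (1.06 ± 0.208), BE692007 (1.04 ± 0.165), Cd7 (0.94 ± 0.208), Ncmap (0.85 ± 0.180), Cd96 (0.75 ± 0.0963) and the ectoenzyme gene Nt5e (0.42 ± 0.0962). Uckl1os (1.93 ± 0.387) is named as an antisense transcript, and its reads cannot be told from those of the opposite strand without a stated strand setting.

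Of the 37 tissue Treg effector genes 6 fell on average (Il10, Cxcr6, Lgals3, S100a6, S100a4 and Klrg1) and 31 did not pass. Adjusted over the list alone, 19 fell (median -0.38, camera adjusted p = 2.96e-10; adjusted p = 0.369 with an estimated correlation). Of the 24 resting lymphoid genes 3 rose (Ccr7, Tcf7 and Klf3). Adjusted over the list alone, 10 rose and 1 fell (median 0.35, camera adjusted p = 3.56e-06; adjusted p = 0.351 with an estimated correlation). The PPAR target list was lower (median -0.17, camera adjusted p = 0.0202; adjusted p = 0.424 with an estimated correlation) with Plin2 as its 1 member past the threshold. Fatty acid oxidation was lower (median -0.16, camera adjusted p = 0.00792; adjusted p = 0.424 with an estimated correlation) with none past it by edgeR. The interferon list was higher (2 of 31 rose, Oas3 and Ifi27l2a, median 0.28, camera adjusted p = 4.07e-05; adjusted p = 0.424 with an estimated correlation). The stress list was lower (2 of 32 fell, Dusp2 and Gadd45b, median -0.19, camera adjusted p = 2.82e-05; adjusted p = 0.351 with an estimated correlation).

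In all, 98 genes were called for the averaged effect, 37 higher and 61 lower, against 1172 at an unadjusted p under 0.05 (531 higher and 641 lower), and an additive model of tissue and genotype, chosen after seeing the data, called 44. In that model Plin2, Cxcr6 and Ccr7 each had an edgeR adjusted p of 0.0962 and Tcf7 had 0.744. Of 39 named genes past the threshold for the averaged effect, 7 kept their calls in every alternative. The count was 52 without KO skin replicate 1, 54 without KO spleen replicate 2, and 49 and 52 without WT spleen replicates 1 and 2. The call of Cxcr6 ended without KO skin replicate 1 or 2 or WT spleen replicate 1 or 2 (edgeR adjusted p = 0.112, 0.122, 0.132 and 0.135). The call of Ltb4r1 ended without any 1 of WT spleen replicates 1 and 2 and KO spleen replicates 1 and 2 (0.222, 0.212, 0.142 and 0.227), and that of Iigp1 without WT spleen replicate 1 or 2 (0.0608 and 0.0574).

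Skin and spleen effects were then compared with each other. Tcf7 rose 4.14-fold in KO skin, while in spleen it was at 291 ± 16.6 CPM in WT and 338 ± 15.3 CPM in KO (difference of log2 effects, skin minus spleen, 1.83 ± 0.284 SE, edgeR adjusted p = 0.0202). Psmd3 rose in KO skin (22.9 ± 11.9 to 60.1 ± 10.6 CPM) and fell in KO spleen (183 ± 10.5 to 51.5 ± 13.1 CPM, difference 3.23 ± 0.397, edgeR adjusted p = 0.0114). The same crossing held for the valine tRNA ligase gene Vars (90.5 ± 25 to 171 ± 28.7 CPM in skin and 176 ± 9.19 to 79.7 ± 9.37 CPM in spleen, difference 2.06 ± 0.253, edgeR adjusted p = 0.00446). Jup fell in KO skin and was at 11.4 CPM in WT and 6.83 CPM in KO spleen (difference -2.95 ± 0.517, edgeR adjusted p = 0.0257).

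The difference passed for 12 genes, against 1178 at an unadjusted p under 0.05 (739 positive and 439 negative). It was positive for 9, the others being Rrs1 (3.61 ± 0.530), Unc119b (1.94 ± 0.338), Zdhhc3 (1.58 ± 0.261), the ubiquitin ligase gene Peli1 (1.45 ± 0.242), Cd96 (1.18 ± 0.192) and Tpi1 (0.89 ± 0.146). It was negative for 3, the others being the peptide receptor gene Calcrl (-1.89 ± 0.326) and the stress response gene Sesn1 (-1.03 ± 0.176). Values that did not pass were Izumo1r (1.11, edgeR adjusted p = 0.0649), Wls (-1.59, 0.0717), Ell (-1.74, 0.0717), Klf6 (-0.61, 0.0717), Klf7 (-1.47, 0.0803), Golga2 (-1.15, 0.081), Zfp36 (-1.13, 0.0863) and Zbtb38 (-0.87, 0.0866). Pparg (0.30, 0.845) and Foxp3 (-0.31, 0.668) did not pass.

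The T helper list differed between tissues as a group (15 tested, none past the threshold alone by edgeR, 3 higher adjusted over the list alone, median 0.82, camera adjusted p = 0.00774; adjusted p = 0.354 with an estimated correlation, and 0.0455 by fry). The B cell list did so too (6 tested, median 1.26, camera adjusted p = 0.00774; adjusted p = 0.354 with an estimated correlation), as did the chemokine and homing receptors (29 tested, median 0.26) and the CD8 T and NK cell markers (6 tested, median 1.23), both with a camera adjusted p of 0.0427 and an adjusted p = 0.895 with an estimated correlation. The count of 12 genes became 2, 1 and 3 without WT skin replicate 1, KO skin replicate 1 or KO skin replicate 2, 2 without WT spleen replicate 2, 146 without WT skin replicate 2 and 145 without KO spleen replicate 1. DESeq2 called 90 and limma-voom 59. With DESeq2 these included the 8 genes from Izumo1r to Zbtb38 above, which edgeR did not call. Vars kept its call in each alternative. Without KO skin replicate 1, Tcf7, Psmd3 and Jup had an edgeR adjusted p of 0.113, 0.106 and 0.122, and without KO skin replicate 2 of 0.0604, 0.0604 and 0.124. Tcf7 and Jup also lost their calls without WT skin replicate 1 (0.113 and 0.195), Tcf7, Psmd3 and Jup without WT spleen replicate 2 (0.0867, 0.078 and 0.0868), and Jup without WT spleen replicate 1 or KO spleen replicate 2 (0.0663 and 0.147).

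The genes called lower in both tissues were Pparg, Frmd5, Gpt2, Itga1, Nkg7 and the transcriptional repressor gene Zbtb32. These 6 compare with 0.2 from independent lists (Fisher's exact test, one-sided p = 3.96e-08). Pparg, the deleted gene, is among the 6. Iigp1 was called higher in both, and Psmd3 and Vars were called higher in skin and lower in spleen. These 2 opposite calls also exceeded the 0.104 from independent lists (Fisher's exact test, one-sided p = 0.00481). Calls in both tissues come from the same fit and share its variance estimate for each gene, so the lists are not independent. The overlap p-values therefore do not alone show a shared genotype effect. Of the 73 genes lower in KO skin, 51 had the same sign in spleen, as did 27 of the 38 higher in KO skin, and 15 of the 34 genes lower in KO spleen had the same sign in skin. Across all 12414 genes, which are not independent replicates, the log2 effects of the tissues had a Pearson r of 0.0651 and a Spearman rho of 0.00865. When genotype labels were swapped within tissues, 3 of the 9 assignments, the real one included, gave a correlation of log2 CPM differences at least as large in size. The largest, 0.136 against 0.058 for the real labels, was the split by replicate number in both tissues, which is also the split by sex. In 50 simulations with no genotype effect, the correlation of log2 effects ran from -0.0447 to 0.0494. Genes were drawn independently in them, so noise common to many genes could widen this range.

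**Figure D3:**
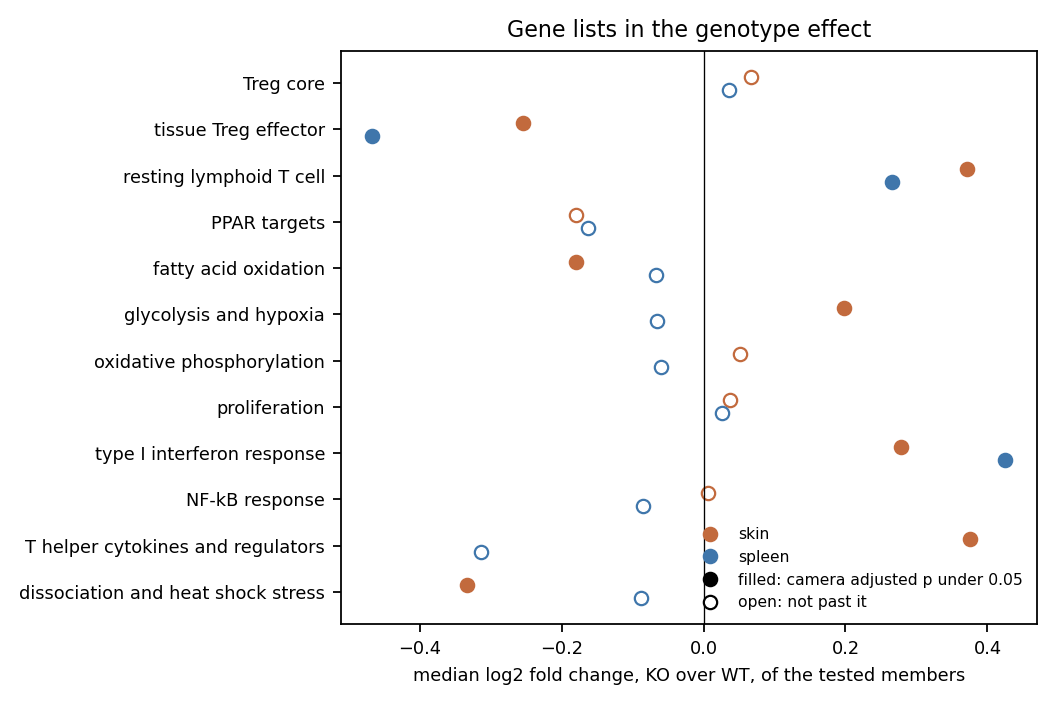
Median log2 fold change of KO over WT for the tested members of 12 gene lists, in skin and in spleen, with filled points for a camera adjusted p under 0.05 at the preset correlation. The tissue Treg effector list lies below 0 and the resting lymphoid and interferon lists lie above 0 in both tissues.

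Tissue set the larger differences. In WT, Tregs of skin against spleen had the inducible heat shock gene Hspa1a at least 1950-fold higher (735 ± 156 against 0 CPM, SD, n = 2), with Hspa1b, a near-identical copy whose reads are uncertain, at least 163-fold higher. Il10 was at 1189 ± 372 against 8.96 ± 1.09 CPM, Areg at 380 ± 170 against 1.04 ± 0.148 CPM, and the cell cycle inhibitor gene Cdkn1a at 315 ± 21.7 against 2.48 ± 0.534 CPM. On the spleen side, the survival gene Bcl2 was at 369 ± 8.82 against 6.82 ± 0.924 CPM, Ccr7 at 708 ± 60.9 against 39.0 ± 5.68 CPM, and Tcf7 at 291 ± 16.6 against 7.98 ± 4.31 CPM. Pparg (log2 fold change 1.92, edgeR adjusted p = 0.000121) and Foxp3 (0.91, edgeR adjusted p = 4.87e-05) were higher in skin.

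Also higher in WT skin were Col18a1 (643-fold, 95% interval 178 to 5310, 2 counts in spleen), Ltf (198-fold, 67.5 to 965, 3 counts), Atf3 (log2 6.64 ± 0.428 SE), Ctla2a (6.39 ± 0.344), the orphan nuclear receptor gene Nr4a2 (6.10 ± 0.448), Fosl2 (6.09 ± 0.333) and Gem (6.08 ± 0.212). Also higher in WT spleen were Treml2 (log2 -6.45 ± 0.364), Igfbp4 (-6.33 ± 0.400), Atp1b1 (-5.99 ± 0.313), Gsta4 (-5.92 ± 0.335), Art2b (-5.87 ± 0.276), Gata1 (-5.77 ± 0.677), P2rx7, a receptor for extracellular ATP (-5.18 ± 0.342), Dtx1 (149-fold, 50.7 to 725), Arhgap20 (123-fold, 33.8 to 1020), Gabrr2 (at least 55.4-fold) and St8sia1 (at least 49.2-fold).

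All 40 proliferation genes were higher in WT skin, with Top2a at 677 ± 41.1 against 232 ± 23.3 CPM (median log2 1.4, camera adjusted p = 4.38e-18; adjusted p = 0.0989 with an estimated correlation). Of 24 glycolysis and hypoxia genes 23 were higher, with Aldoa at 3737 ± 166 against 516 ± 0.941 CPM (median 2.24, camera adjusted p = 3.4e-16; adjusted p = 0.0451 with an estimated correlation). Of 37 tissue Treg effector genes 35 were higher (median 2.31, camera adjusted p = 3.15e-22; adjusted p = 0.0522 with an estimated correlation). Of 24 resting lymphoid genes 21 were lower and Il7r was higher (median -3.14, camera adjusted p = 8.37e-14; adjusted p = 0.0451 with an estimated correlation). Of 24 NF-kB response genes 18 were higher, with Nfkbia at 4468 ± 49.0 against 463 ± 78.2 CPM (median 1.37, camera adjusted p = 3.74e-09; adjusted p = 0.0451 with an estimated correlation). Interferon genes were lower in 18 of 31 cases (median -0.89, camera adjusted p = 7.68e-05; adjusted p = 0.278 with an estimated correlation). Of 32 stress genes 25 were higher and Dusp2 was lower (median 1.86, camera adjusted p = 2.79e-14; adjusted p = 0.0451 with an estimated correlation), so each of these groups moved together with the marker of handling. Of 22 Treg core genes 14 were higher and 5 lower (camera adjusted p = 0.00595; adjusted p = 0.0989 with an estimated correlation), with the inhibitory receptor gene Ctla4 at 3056 ± 267 against 328 ± 9.66 CPM and Izumo1r at 38.2 ± 4.22 against 496 ± 0.264 CPM. The mast cell and basophil list was higher (4 tested, 2 past the threshold, Kit and Il4, camera adjusted p = 0.00891; adjusted p = 0.242 with an estimated correlation). T cell receptor signalling genes were higher (17 of 30 higher, 6 lower, median 0.89, camera adjusted p = 0.000126; adjusted p = 0.0522 with an estimated correlation). PPAR targets were higher (9 of 24 higher, 2 lower, median 0.30, camera adjusted p = 0.0224; adjusted p = 0.276 with an estimated correlation), with Plin2 at 296 ± 88.6 against 35.3 ± 9.56 CPM. Langerhans and dendritic cell genes were higher (Cd74, Epcam and Xcr1 of 6 tested, camera adjusted p = 0.0465; adjusted p = 0.252 with an estimated correlation).

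In WT, edgeR called 3944 genes between the tissues, 2059 higher in skin and 1885 higher in spleen, and requiring more than a 1.5-fold change left 1877.

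In KO the same contrast gave similar leading genes. Hspa1a was at least 1240-fold and Hspa1b at least 131-fold higher in skin, Il10 was at 327 ± 3.71 against 4.35 ± 1.57 CPM, Areg at 149 ± 6.13 against 0.642 ± 0.237 CPM, and Tcf7 at 33.0 ± 1.49 against 338 ± 15.3 CPM (SD, n = 2). Ier3 was 427-fold (95% interval 76.2 to 16900), Hk2, which starts glycolysis, 316-fold (56.2 to 12500), Pcsk1 256-fold (45.4 to 10100) and Ltf 199-fold (54.6 to 1650) higher in skin. Pparg (log2 2.22, edgeR adjusted p = 0.000462) and Foxp3 (0.60, edgeR adjusted p = 0.00248) were again higher in skin. Nr4a2 (6.77 ± 0.487 SE), Fosl2 (6.74 ± 0.375), Cdkn1a (5.98 ± 0.219) and Gem (5.63 ± 0.215) followed. On the spleen side were Treml2 (-6.72 ± 0.353), Igfbp4 (-5.96 ± 0.367), Gpr83 (-5.83 ± 0.608), Bcl2 (-5.51 ± 0.168), Gsta4 (-5.20 ± 0.299), Atp1b1 (-5.06 ± 0.283), Tdrp (-5.00 ± 0.433), Ncf1 (-4.86 ± 0.500), Art2b (-4.80 ± 0.247), Dtx1 (-4.73 ± 0.407), St8sia6 (-4.52 ± 0.245) and Selp (at least 49.9-fold).

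All 40 proliferation genes were higher in KO skin too (camera adjusted p = 1.07e-18; adjusted p = 0.0758 with an estimated correlation), as were 23 of 24 glycolysis and hypoxia genes (1.92e-18; adjusted p = 0.032 with an estimated correlation) and 36 of 37 tissue Treg effector genes (1.07e-24; adjusted p = 0.0434 with an estimated correlation). Resting lymphoid genes were lower in 22 of 24 cases (2.28e-15; adjusted p = 0.032 with an estimated correlation). Of 32 stress genes 26 were higher and 2 lower (camera adjusted p = 2.37e-14; adjusted p = 0.032 with an estimated correlation). T helper genes were higher as a list (8 of 15 higher, Cxcr5 lower, camera adjusted p = 0.000319; adjusted p = 0.0603 with an estimated correlation), with Ccr6 at 234 ± 19.3 against 40.3 ± 15.1 CPM. NF-kB genes (18 of 24 higher, camera adjusted p = 1.08e-09) and T cell receptor signalling genes (21 of 30 higher, 5 lower, 5.24e-06) were higher, both with adjusted p = 0.032 with an estimated correlation. Chemokine and homing receptors were higher (16 of 29 higher, 7 lower, camera adjusted p = 0.00354; adjusted p = 0.205 with an estimated correlation), and so were Treg core genes (13 of 22 higher, 4 lower, 0.0029; adjusted p = 0.0758 with an estimated correlation). Interferon genes were lower (18 of 31 lower, Isg20 higher, camera adjusted p = 5.24e-06; adjusted p = 0.214 with an estimated correlation). The lists of Langerhans and dendritic cells (5 of 6 higher, camera adjusted p = 0.00154; adjusted p = 0.114 with an estimated correlation) and of mast cells (Kit and Il4 of 4, 0.0122; adjusted p = 0.205 with an estimated correlation) were higher.

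In KO, edgeR called 3596 genes, 2019 higher in skin and 1577 higher in spleen, and requiring more than a 1.5-fold change left 1707. Both genotypes shared 1489 genes higher in skin and 1035 higher in spleen, against 335 and 240 from independent lists. In opposite directions 5 genes were called, Klf7 higher in WT skin and KO spleen, and Baz1b, Med30, Tram1 and Vars the reverse.

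The genes that distinguish skin from spleen Tregs moved in KO skin. The stress list, a marker of handling, was likewise higher in WT skin than in WT spleen and lower in KO skin. A handling difference was not separated from this shift. Of the 73 genes lower in KO skin, 63 were among those higher in WT skin than in WT spleen, among them Il10, Areg, Plin2, Jup and Pparg. Of the 38 higher in KO skin, 32 were among those higher in WT spleen, among them Tcf7, Ccr7 and Cd96. These overlaps share the WT skin libraries, whose noise adds to them. With the tissue contrast taken in KO, where the shared KO skin libraries act the other way, the overlaps were 48 of 73 and 24 of 38, against 11.9 and 4.83 from independent lists. The 200 skin-high genes had a median log2 fold change of -0.29 in KO against WT skin (camera p = 6.61e-16, and p = 0.00146 with an estimated correlation). The 200 spleen-high genes had a median of 0.42 (camera p = 5.07e-24, and p = 0.000152 with an estimated correlation). Both sets are defined with the WT skin libraries that also enter the genotype contrast. In 50 simulations with no genotype effect the medians ran from -0.07 to 0.02 and from 0 to 0.10. Each gene was drawn independently there, so noise common to many genes could widen these ranges. With the sets defined in KO libraries, which pulls the other way (simulated medians -0.01 to 0.07 and -0.10 to 0), the medians were -0.19 and 0.19.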

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

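The tests of a mixture of spleen-type Tregs, of GC content, of scaling and of the share of skin-type Tregs were chosen only after the result was seen. The tests of other splits, of shared libraries and of the skin-high genes in spleen were set before it.

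Of the genes whose genotype effect differed between skin and spleen by edgeR's interaction test, log2 effects in skin minus spleen were 3.61 for Rrs1, 3.23 for Psmd3, 2.06 for Vars, 1.94 for Unc119b, 1.83 for Tcf7, 1.58 for Zdhhc3, 1.45 for Peli1, 1.18 for Cd96 and 0.889 for Tpi1, and -2.95 for Jup, -1.89 for Calcrl and -1.03 for Sesn1. A trend with GC content between libraries could create such differences, since it moves genes of like composition together. With a GC offset per library, 12 of the 12 genes were still called, which argues against that trend as the whole cause. A biological difference between the tissues stays open and was not tested further.

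In KO skin, skin-high genes were lower and spleen-high genes were higher. The stress list, a marker of handling, moved with the skin-high genes, and a handling difference was not tested. Libraries shared by the signature and the contrast gave, with no effect, a lowest median of -0.0691 for skin-high and a highest of 0.098 for spleen-high genes. The observed medians were -0.29 and 0.42. These simulations drew each gene independently, so they lack noise common to many genes and do not decide alone. Sets defined in KO libraries, where sharing pulls the other way, had medians of -0.19 and 0.19, which argues against sharing as the whole cause. Noise common to many genes in a library stays open. Spleen-type Tregs mixed into KO skin would bring their abundant transcripts at 1 share. The most spleen-specific abundant genes showed an upper quartile of 4.04%, where the genes called higher needed 15% to 52.6% (lower to upper quartile). The latter were called in the same skin libraries, which inflates the share they need, and they were not read in held-out libraries. That comparison therefore does not decide alone. A mixture stays open for the genes called higher, Ccr7 (6.39%) and Tcf7 (7.78%) included. For genes ranked lowest in 1 WT and 1 KO skin library, the other skin libraries lay below a mixture of 16.2%, with median log2 ratios of -0.549 and -0.74 (upper quartiles -0.254 and -0.267), which argues against a mixture as the whole cause of the drop. For the 200 spleen-high genes defined in KO libraries the share had a lower quartile of -1.19% and a median of 3.05%, so a small mixture and a change within skin Tregs cannot be told apart there, since the genes go both ways. The mixture tests used only the KO spleen profile. A loss or gain of another kind of cell in KO skin stays open and was not tested.

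In spleen, 34 of 35 called genes were lower in KO, against 631 of 972 at an unadjusted p under 0.05 and 6251 of all 12414. With a GC offset 31 were lower, and under the other scalings at least 96.6% of the calls were lower, which argues against a GC trend and the scaling as the cause of the direction among called genes. Fewer Tregs with the profile of WT skin in KO spleen could lower skin-high genes, which had a median of -0.116 in spleen (quartiles -0.32 and 0.05; -0.168 for those defined in KO) against -1.24 for the called genes, but the bound set beforehand for excluding this loss was above -0.1, so this test alone does not decide. In the test of shares, chosen after the result was seen, the most skin-specific abundant genes lost a share with an upper quartile of 3.84%. The genes called lower needed 23.7% or more (lower quartile), but they were called in the same spleen libraries, which inflates the share they need. The test of shares therefore does not decide alone either, and this loss stays open. Of the 34, 19 were higher in WT spleen than in WT skin, but the calls share the WT spleen libraries, whose noise adds to this count. With the tissue contrast in KO, where the shared KO spleen libraries act the other way, 0 were higher in spleen and 15 in skin. These counts therefore do not decide. A change within spleen Tregs and the loss of another kind of cell stay open and were not tested.

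For the averaged effect the real split called 98 genes. Splits that put 3 libraries of a tissue against 1 test another contrast, so only the 18 splits with 2 skin and 2 spleen libraries in each group, 1 of them the real one, are compared, a choice made after the result was seen. These are too few for a share under 0.05. The highest of the other splits called 12 genes and is the interaction contrast.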

How the results depend on the processing

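The fits without robust estimation, with a GC offset and with the additive model were tests chosen only after the result was seen. No call of a named gene changed direction. The side of the threshold held for 6514 comparisons of a named gene with an alternative, 627 lost their call and 66 gained one. Where neither fit passed, a change of direction was counted as held. Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested except where the alternative itself tests more genes, asks for a larger change or uses fewer libraries. Without a low-count filter counts were 344 in skin, 154 in spleen, 288 averaged and 233 for the interaction. Against a fold threshold of 1.5 they were 20, 4, 13 and 3, and 1877 in WT and 1707 in KO between tissues. Spleen gave 75 with DESeq2 and 57 with limma-voom and quality weights, the interaction gave 90, 59 with limma-voom and 64 with weights, and the additive model gave 44 for the average. Leaving out 1 library gave 29 to 209 genes in skin, 7 to 119 in spleen, 49 to 142 averaged and 1 to 146 for the interaction, with the lone library of a group assumed to vary like the others. The correlation between tissues ran from 0.0339 to 0.0748.

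Gene lists depend on the test. With an estimated correlation 0 lists passed in skin, in spleen, averaged or for the interaction, 4 between tissues in WT and 6 in KO, against 8, 3, 6, 4, 12 and 13 with camera's preset. With fry the counts were 0, 0, 0, 1, 20 and 20.

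Replicate numbers tie the samples by sex but are not taken as pairs of 1 animal. Deviations of same-numbered libraries correlated between 0.0283 and 0.112, and between -0.0314 and 0.0518 without sex-linked genes. With the number as a block the counts were 135, 51, 109, 16, 3911 and 3584, and 2 lists for the interaction. A block within genotype gave 121 interaction genes, 8 named genes gaining a call. Depth limits genes near the floor of 3 counts per group (0.379 to 0.437 CPM).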

Other observations

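The comparison of replicate numbers was chosen only after the result was seen.

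Replicate 1 of each group carried Xist, the RNA of the inactive X chromosome, at 453 to 554 CPM and no reads of the Y genes Ddx3y, Uty, Kdm5d and Eif2s3y, while replicate 2 carried these Y genes and at most 1 count of Xist. The sexes implied by these genes were therefore balanced over genotype and tissue. In the model with the number as a factor, edgeR called 11 genes between the numbers, 2 on the X, 4 on the Y and 5 on autosomes. Besides Xist and the Y genes, Kdm6a on the X was lower in replicate 2 (log2 -0.75, edgeR adjusted p = 0.00877), and so were Nap1l1 (-0.74, 0.000202), Il1rl1, the IL-33 receptor of tissue Tregs (-0.67, 0.009), and Gpr15, a homing receptor (-1.01, 0.0279). H2-Q6, of a family with near-identical copies, was higher in replicate 2 (0.52, 0.0358). These genes were chosen after their values were seen.

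Cyp11a1, a steroid-making enzyme found in mast cells and some activated T cells, was at 164 and 29.9 CPM in WT skin replicates 1 and 2, and its mean was 96.8 ± 94.7 CPM in WT skin and 8.96 ± 10.1 CPM in KO skin (SD, n = 2, edgeR adjusted p = 0.462). The mitochondrial genome was read unevenly, with 6 of its 13 listed genes at 3 counts or fewer in every library. The mitochondrial share of counts was 1.36% to 1.76%.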
